A study of Mus musculus with 6 samples.

How the data were processed

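Total RNA of MSU-treated bone-marrow-derived mouse macrophages was sequenced as 6 libraries, 3 labelled Tet2 knockout and 3 labelled wild-type. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy Plus Mini column and libraries were made with the NEBNext Ultra RNA kit for Illumina. The submitters' processing notes name fastp (read trimming), STAR (alignment), featureCounts (counting per gene) and the mouse build mm10, without versions. The deposited values are whole-number read counts per gene, not normalised, with gene symbols, types and coordinates beside them. The strand setting of the counting is not given in the sources used here, and the kit as labelled does not mark strand, so reads from a gene and from an overlapping antisense gene cannot be told apart. Reads shared by near-identical copies can be assigned to either copy or left out, which makes the values of such genes uncertain. All 6 count columns matched a sample by name, and every row named a gene.

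Groups were taken from the genotype labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10), which left 13175 of 54532 genes, libraries were scaled by TMM, and groups were compared with the robust quasi-likelihood test, genotype being the only term. P-values were adjusted by the Benjamini-Hochberg method and 0.05 was the threshold. Log2 fold changes are the libraries labelled knockout minus those labelled wild-type, with a prior count of 0.125, and levels are TMM-scaled CPM with the SD over 3 libraries. An exact permutation test of 3 against 3 cannot go below p = 0.1, so single values were tested only in the model across all genes.

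Gene lists were fixed before the data were examined: 28 process lists, 12 lists of cell type markers and 4 technical lists. Lists of the first 2 kinds with at least 5 tested members, 34 in all, were tested with camera in limma 3.58.1, which compares a list with the other genes, at a preset correlation of 0.01 between genes. Camera was repeated with an estimated correlation. Lists were also tested with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Ranges of a list's adjusted p over all alternatives are those of camera and leave fry out. Members are counted from the adjusted p over all genes tested and also from p-values adjusted over the list alone. Of 20 tested chemokine genes 5 also stand in another list, and several other lists share members, so lists are not independent of one another.

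The genes named in the text were chosen by a rule fixed before the data were examined. It takes Tet2, 10 fixed genes of gout inflammation, and the 10 largest rises and 10 largest falls among called protein-coding genes with an average log2 CPM of at least 1, a proper symbol and no overlap between groups. It also takes up to 4 members of each list with the smallest p (2 by mean level where none passed), the sex-linked genes, and up to 6 called genes within 10 Mb of Tet2 with the smallest p. Members that fell outside the rule are named where 5 or fewer moved one way, were left uncalled or changed against their list, and these were chosen after their values were seen. A few genes that the rule or these counts would name are not reported here.

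The test was tried on simulated counts drawn from the means and library sizes of the real libraries, for the comparison of 3 libraries labelled knockout with 3 labelled wild-type over 13042 genes. It called 36% of 50 genes changed by a log2 of 0.25, 72% of 50 changed by 0.5, 87.8% of 49 changed by 1 and all of 48 changed by 2, and 1.88% of its calls were unchanged genes. Camera called a simulated list of 25 genes shifted by 0.3 and 0 of 40 unshifted lists. Genes were simulated independently of one another, so this does not try the preset correlation between genes. In the simulation 12820 of 13042 genes were unchanged, whereas 40.9% of tested genes were called in the data. The adjusted p is stricter where fewer genes change, so the shares called do not carry over to the real comparison. The simulated spread was the one fitted to these libraries, so the simulation cannot show whether that spread is biological.

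Alternatives planned in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, protein-coding genes only, the replicate number as a block, each library left out in turn, and the other list tests. Added after the data had been seen were removal of trends with transcript GC content and length (GENCODE M21 transcripts), an assumed biological coefficient of variation of 0.1, and leaving out mitochondrially encoded genes or genes within 10 Mb of Tet2. Camera took the counts in the main test but log2 values with DESeq2, limma-voom and the trends removed. A list call that changed there may reflect that input as much as the alternative named. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Total counts were 14481843, 14287850 and 13425170 in knockout replicates 1 to 3 and 13881435, 11997104 and 13704629 in wild-type replicates 1 to 3. A count of 0 allows up to 3 counts, which is 0.207 to 0.250 CPM in these libraries and covers counting error only.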

Results

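RNA sequencing measured gene expression in bone-marrow-derived macrophages, phagocytic cells grown from mouse marrow, that had been exposed to monosodium urate (MSU), the crystal that sets off gout. The 6 libraries fell into 2 groups of 3, cells labelled Tet2 knockout and cells labelled wild-type. Tet2 encodes an enzyme that oxidises methylated cytosine in DNA, and its loss in blood cells is a common form of clonal hematopoiesis. Every library came from MSU-treated cells, so the comparison concerned the genotype label within the treated state, and the response to MSU itself was not analysed here. The deposited table held 54532 genes, and total counts ran from 11997104 in wild-type replicate 2 to 14481843 in knockout replicate 1. Within groups the libraries correlated with Pearson r between 0.9932 and 0.9946 across genes, and between groups with r from 0.9836 to 0.9855. No pair of libraries was close enough to be one library deposited more than once, since counts within a group still differed by 1.55 to 2.32 times the variance of sampling noise. Wild-type replicate 2, which had the lowest total and the lowest mitochondrial share (0.240%), stood apart from the other 2 wild-type libraries: its 2 pairs within the group reached 2.30 and 2.32 times that variance, against 1.55 to 1.73 for the other pairs, and the second principal component (12.2% of the variance) placed it at 18.8 and them at -10.4 and -9.21. The labels do not say that libraries of a group came from separate mice or cultures, so p-values here measure only the spread between these libraries, which may be technical.

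Tet2 (ENSMUSG00000040943, mm10 chromosome 3, positions 133463679 to 133545139, minus strand) was read first, as a check of the labels. Its normalised level was 33.7 ± 0.80 CPM (SD, n = 3) in the libraries labelled knockout and 29.3 ± 1.41 CPM (SD, n = 3) in those labelled wild-type, a log2 difference of 0.20 (SE 0.07; edgeR adjusted p = 0.0159). Raw counts were 467, 482 and 450 in the libraries labelled knockout and 413, 338 and 427 in those labelled wild-type. The call was lost without knockout replicate 2 (edgeR adjusted p = 0.0553) and without wild-type replicate 2 (0.0799), with DESeq2 (0.112), with GC and length trends removed (0.180) and with an assumed spread of 0.1 (0.350), and ranged from 0.0143 to 0.350 over all alternatives. A gene-level count that covers all exons cannot show a partial deletion, and the allele is not given in the labels. Because the target gene was not lower, directions are given throughout as those of the libraries labelled Tet2 knockout relative to those labelled wild-type.

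Interferon-induced genes, genes of the interferon-gamma response and genes of cholesterol synthesis were higher in the libraries labelled Tet2 knockout. Rsad2, an antiviral radical SAM enzyme, stood at 1870 ± 7.35 against 1315 ± 15.7 CPM (SD, n = 3 each), and Msmo1, an enzyme of sterol synthesis, at 65.7 ± 2.71 against 43.4 ± 1.25 CPM. Chemokines split, with the monocyte attractants Ccl2 and Ccl12 higher and the neutrophil attractants Cxcl1 and Cxcl2 lower. Il1b, the cytokine central to gout flares, rose by 0.32 on the log2 scale while Il1a and Nlrp3 fell. Itgax, which encodes the integrin CD11c, and Dio2, the thyroid hormone activating deiodinase, were among the largest falls.

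Across the genome 5385 of 13175 tested genes (40.9%) passed an edgeR adjusted p of 0.05, with 2852 higher and 2533 lower. Most changes were small, with a median absolute log2 change of 0.29 among these genes. At least a 2-fold change was seen in 320 of them, 226 higher and 94 lower. The 3 libraries of one group did not overlap the 3 of the other in 5037 of the called genes, and 47.8% of all tested genes had no such overlap, where chance gives 10%. The number rests on a very small spread between libraries, a common biological coefficient of variation of 2.63%. With a spread of 0.1 assumed instead, an alternative added after the data had been seen, 1885 genes passed, 1222 higher and 663 lower. Mitochondrially encoded genes took 0.357 ± 0.00865% of counts in the libraries labelled knockout and 0.261 ± 0.0186% in those labelled wild-type (SD, n = 3 each).

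The genes chosen in advance for their place in gout inflammation moved in both directions. Il1b rose from 78.7 ± 0.129 to 98.2 ± 2.14 CPM (log2 change 0.32, SE 0.04; edgeR adjusted p = 6.01e-10). Il18, the other cytokine matured by caspase-1, rose from 8.70 ± 0.622 to 13.4 ± 1.45 CPM (log2 change 0.62), and Casp1 itself from 186 ± 4.08 to 272 ± 8.30 CPM (log2 change 0.55). Nlrp3, the sensor of the inflammasome that urate crystals engage, fell from 184 ± 3.21 to 146 ± 1.98 CPM (log2 change -0.34), and Il1a from 71.9 ± 2.07 to 44.0 ± 1.36 CPM (log2 change -0.71). Il6 fell from 15.6 ± 0.988 to 12 ± 1.41 CPM (log2 change -0.37; edgeR adjusted p = 0.00206). Tnf stood at 115 ± 7.95 and 112 ± 5.94 CPM, a difference smaller than the spread (log2 change 0.03; edgeR adjusted p = 0.600). Ccl2 rose from 209.7 ± 2.30 to 304 ± 0.391 CPM (log2 change 0.54), whereas Cxcl1 and Cxcl2 fell by 0.39 and 0.34 on the log2 scale. With the assumed spread of 0.1, Il1b (edgeR adjusted p = 0.0594) and Il6 (0.0667) no longer passed.

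**Figure D1:**
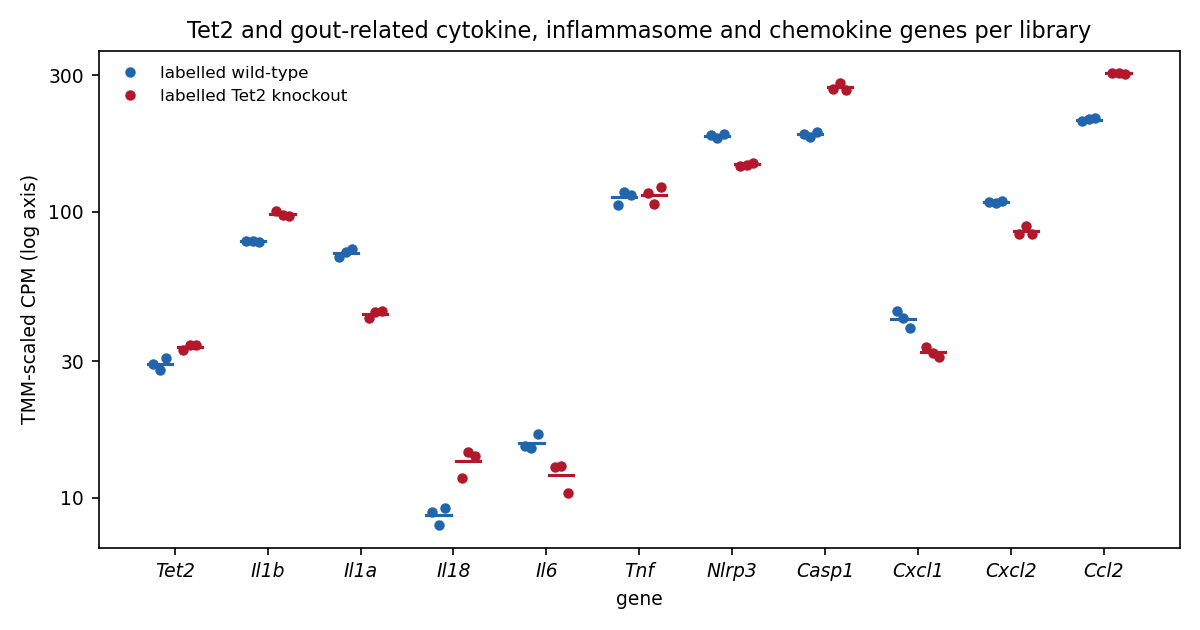
Normalised level in TMM-scaled CPM, on a log axis, of Tet2 and the 10 genes fixed in advance in each of the 6 libraries; points are libraries and short lines are group means of 3. Tet2 was not lower in the libraries labelled knockout, Il1b, Il18, Casp1 and Ccl2 were higher, Il1a, Il6, Nlrp3, Cxcl1 and Cxcl2 were lower, and the Tnf points overlap.

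The largest rises by the rule fixed in advance were in Lrmda (log2 change 3.46, SE 0.23), a melanocyte differentiation gene, Gdf3 (2.93, SE 0.13), a ligand of the TGF-beta family, and Slc9a9 (2.29), an endosomal sodium-proton exchanger. Pgm5, the endothelial lipase gene Lipg, the membrane-bound protease gene Mmp25, the potassium channel subunit gene Kcnab1, the endothelin receptor gene Ednrb, Ifit1bl1 and Ccl12 followed with log2 changes from 2.25 down to 2.07. Ednrb went from 15.2 ± 0.597 to 68.8 ± 1.30 CPM and Gdf3 from 3.19 ± 0.451 to 24.4 ± 1.16 CPM (SD, n = 3 each). The largest falls were in Pira2 (log2 change -3.51, SE 0.11), Lmbr1 (-3.23, SE 0.22) and Dio2 (-2.16, SE 0.04), which went from 237 ± 8.38 to 53.1 ± 1.37 CPM. Tm4sf19, Cadm4, Itgax, Mcub, F7, Hilpda and Aqp1 fell by between 1.83 and 1.43 on the log2 scale, among them Hilpda, a lipid droplet protein gene induced by hypoxia, from 120.1 ± 2.97 to 44.0 ± 2.15 CPM, and Itgax from 30.7 ± 2.09 to 9.41 ± 0.640 CPM. The values of Pira2 and Ifit1bl1 are uncertain because each has close paralogs that can share reads. The rule took only genes that passed an edgeR adjusted p of 0.05 with no overlap between the groups, so both hold for all 20 by choice.

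Among genes induced by type I interferon, 31 of 38 tested members rose and 3 fell (camera adjusted p = 1.99e-23). Cmpk2, a nucleotide kinase, rose from 691 ± 7.46 to 1214 ± 12.2 CPM, Oasl1 by 1.56 and the antiviral gene Ifit2 by 0.63 on the log2 scale. The 3 that fell were Bst2 (-0.14), Usp18 (-0.14) and Irf9 (-0.12), the last a component of the factor that drives this response. Of the interferon-gamma response and guanylate-binding genes, 24 of 26 rose, Cd274 fell (log2 change -0.34) and Gbp8 did not pass (camera adjusted p = 3.08e-14). The immunity-related GTPase genes Iigp1 and Irgm1 rose by 1.41 and 0.42, and Tgtp2, which has a near-identical copy and is uncertain, by 1.04. Gbp2, Gbp3, Gbp5 and Gbp7 of this list lie within 10 Mb of Tet2, and without the genes of that stretch 21 members passed (camera adjusted p = 1.22e-11). Both lists were also called with an estimated correlation, with adjusted p = 0.00911 and adjusted p = 0.0150. The counts were equal when adjusted over the list alone. In all 19 genes of the first list and 14 of the second passed with the assumed spread of 0.1, and Bst2 (edgeR adjusted p = 0.483), Usp18 (0.504), Irf9 (0.594), Gbp3 (0.275) and Gbp5 (0.403) no longer did.

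Cholesterol synthesis genes moved one way, with 20 of 23 tested members higher and none lower (camera adjusted p = 8.10e-09; adjusted p = 0.0275 with an estimated correlation). Srebf2, the transcription factor that drives the pathway, rose from 109.9 ± 1.61 to 168 ± 6.47 CPM and its retention partner Insig1 by 0.69 on the log2 scale, while Dhcr7 and Ebp were among the members that did not pass. Among targets of the liver X receptor 8 of 13 rose and 3 fell (camera adjusted p = 0.0410; adjusted p = 0.208 with an estimated correlation). Lpl, lipoprotein lipase, rose from 2592 ± 14.7 to 4428 ± 24.0 CPM, and Scd2 and the receptor gene Nr1h3 rose by 0.57 and 0.54. The 3 that fell were the cholesterol exporters Abca1 (-0.47) and Abcg1 (-0.37) and the ubiquitin ligase gene Mylip (-0.49). The liver X receptor call was lost with upper-quartile scaling (camera adjusted p = 0.0671), DESeq2 values (0.188), limma-voom (0.0789) and GC and length trends removed (0.194). It was also lost without knockout replicate 2 (0.0956) and without wild-type replicates 1 (0.0599), 2 (0.106) and 3 (0.0582), and ranged from 0.00478 to 0.208 over all alternatives. Counts for both lists were equal when adjusted over the list alone, and with the assumed spread of 0.1 they were 13 and 8.

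Chemokine genes rose in 12 of 20 tested members and fell in 5 (camera adjusted p = 1.49e-07; adjusted p = 0.0594 with an estimated correlation), or 13 and 5 when adjusted over the list alone. Ccl9 rose from 963 ± 17.7 to 1643 ± 37.1 CPM, Ccl5, an attractant of T cells and monocytes, by 0.95, and the interferon-induced Cxcl10 by 1.14 on the log2 scale. The 5 that fell were Cxcl1, Cxcl2, Cxcl3 (-0.65), Cxcl5 (-0.33) and Cxcl14 (-0.79), of which the first 4 are ligands of the neutrophil receptor CXCR2. Some connective tissue markers were lower in the same libraries as these chemokines and Il6 (Acta2 by 0.53 and Postn by 0.40 on the log2 scale). Cxcl12 and Col3a1 rose, and Pdgfra, Pdgfrb and Thy1 did not pass. Among inflammatory cytokines 8 of 17 rose and 3 fell, the latter Il1a, Il6 and Osm (-0.36), and the list was not called (camera adjusted p = 0.170). Tnfsf10, which encodes TRAIL, rose by 1.83 and Ebi3, a subunit of IL-27 and IL-35, by 0.79. Inflammasome and pyroptosis genes rose in 16 of 24 tested members, and Txnip (-0.81), Il1a, Nlrp3 and Mefv (-0.77) fell. That list was not called (camera adjusted p = 0.306), but passed with DESeq2 values (0.0258) and with GC and length trends removed (0.0217). Its range was 0.0217 to 0.405 over all alternatives but fry. The DESeq2 and trend alternatives gave camera log2 values in place of counts, so the trends alone cannot be credited. By fry the list passed (fry adjusted p = 0.000263). Adjusted over the list alone, the cytokine and inflammasome counts were equal. There were 16 chemokine, 9 cytokine and 11 inflammasome genes that passed with the assumed spread of 0.1, and Il6 did not (edgeR adjusted p = 0.0667).

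Anti-inflammatory mediators rose in 8 of 17 tested members and fell in 3, with equal counts adjusted over the list alone (camera adjusted p = 0.0410; adjusted p = 0.416 with an estimated correlation). Acod1, which makes itaconate, rose from 463 ± 8.66 to 1075 ± 16.8 CPM, and Zfp36, which destabilises cytokine mRNA, by 0.57 on the log2 scale. Gdf15 (-1.01), the interleukin-1 receptor antagonist gene Il1rn (-0.44) and Tnfaip3 (-0.29) fell. The call was lost with upper-quartile scaling (camera adjusted p = 0.0673), DESeq2 values (0.188), limma-voom (0.116) and GC and length trends removed (0.105). It was lost as well without knockout replicates 1 (0.0637) and 2 (0.111) and without wild-type replicates 1 (0.0686), 2 (0.0952) and 3 (0.115), in a range from 0.00345 to 0.416 over all alternatives. A total of 7 members passed with the assumed spread of 0.1, and Tnfaip3 did not (edgeR adjusted p = 0.0845).

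Genes of alternative activation split, with 6 of 12 tested members higher and 5 lower (camera adjusted p = 0.00235; adjusted p = 0.171 with an estimated correlation). The scavenger receptor genes Stab1 and Mrc1 rose by 1.44 and 1.06, while Clec7a (-0.36), Egr2 (-0.67), Klf4 (-0.45), Tgm2 (-0.12) and the arginase gene Arg1 (-0.77) fell. The call was lost with DESeq2 values (camera adjusted p = 0.596), limma-voom (0.320) and GC and length trends removed (0.531), and without knockout replicate 2 (0.0843) or wild-type replicate 2 (0.112), in a range from 1.72e-05 to 0.596 over all alternatives. Scavenger and phagocytic receptors rose in 14 of 25 tested members and fell in 7 (camera adjusted p = 0.00252; adjusted p = 0.148 with an estimated correlation), or 14 and 8 when adjusted over the list alone. C5ar1, the receptor for complement C5a, rose from 171 ± 2.78 to 300.3 ± 4.76 CPM, and Clec4d fell by 0.71 on the log2 scale. This call was lost with DESeq2 values (camera adjusted p = 0.188, the highest over all alternatives) and with GC and length trends removed (0.152), against a lowest value of 3.51e-05. Complement genes rose in 6 of 15 and fell in 1 (camera adjusted p = 0.000336; adjusted p = 0.120 with an estimated correlation), or 7 and 1 when adjusted over the list alone. C3 rose from 145 ± 6.97 to 435 ± 7.46 CPM, Cd55, which shields cells from complement, rose by 1.24, and C1qa was the 1 that fell (-0.83). With the assumed spread of 0.1, 9 alternative activation genes, 11 receptors and 5 complement genes passed, and Tgm2 did not (edgeR adjusted p = 0.595).

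NADPH oxidase genes rose in 5 of 8 tested members (camera adjusted p = 0.0398; adjusted p = 0.229 with an estimated correlation). The cytosolic subunit gene Ncf1 rose by 0.83 and Rac2 by 0.38, whereas Cyba, a membrane subunit gene, fell by 0.44 on the log2 scale. This call was lost with upper-quartile scaling (camera adjusted p = 0.0620), DESeq2 values (0.195), limma-voom (0.0782) and GC and length trends removed (0.155), and without knockout replicate 2 (0.0528) or wild-type replicate 1 (0.0686) or 3 (0.0682), in a range from 0.00345 to 0.229 over all alternatives. Lysosomal and TFEB-linked genes were called lower, with 8 of 27 members higher and 11 lower (camera adjusted p = 0.00342; adjusted p = 0.208 with an estimated correlation), or 9 and 13 when adjusted over the list alone. The protease gene Ctsl fell from 3059 ± 54.1 to 1790 ± 12.3 CPM, and Gpnmb and Lgals3 fell by 0.43 and 0.47. The lysosomal call was lost with DESeq2 values (camera adjusted p = 0.310) and with GC and length trends removed (0.518), the highest of a range that starts at 5.37e-05. Osteoclast genes were called lower with 1 of 7 higher and 3 lower (camera adjusted p = 0.0149; adjusted p = 0.171 with an estimated correlation). The 3 were the proton pump subunit gene Atp6v0d2 (-0.89), Acp5 (-0.64) and the fusion gene Dcstamp (-1.01), while Itgb3 rose by 0.23. The osteoclast call was lost with DESeq2 values (camera adjusted p = 0.402), limma-voom (0.137) and GC and length trends removed (0.497), and without knockout replicate 2 (0.0528) or wild-type replicate 2 (0.0669), in a range from 0.000724 to 0.497 over all alternatives. Under the assumed spread of 0.1, 4 NADPH oxidase, 7 lysosomal and 3 osteoclast genes passed, and Itgb3 did not (edgeR adjusted p = 0.226).

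Glycolysis and hypoxia genes rose in 15 of 26 tested members and fell in 3 (camera adjusted p = 0.00448; adjusted p = 0.227 with an estimated correlation), or 17 and 3 when adjusted over the list alone. Pgk1 rose from 1078 ± 35.7 to 1338 ± 16.8 CPM and the hexokinase gene Hk2 by 0.41, while Hif1a (-0.19), Vegfa (-0.23) and Adm (-0.54) fell. Genes of the G2 and M phases rose in 14 of 27 members and fell in none (camera adjusted p = 0.0137; adjusted p = 0.161 with an estimated correlation), or 15 when adjusted over the list alone. Mki67, a marker of cycling cells, rose from 101 ± 6.41 to 165 ± 3.07 CPM and Ccnb2, a cyclin of mitosis, by 0.66 on the log2 scale. Only 4 genes of each of these lists passed with the assumed spread of 0.1, and Pgk1 (edgeR adjusted p = 0.0555), Hif1a (0.336) and Vegfa (0.208) did not.

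**Figure D2:**
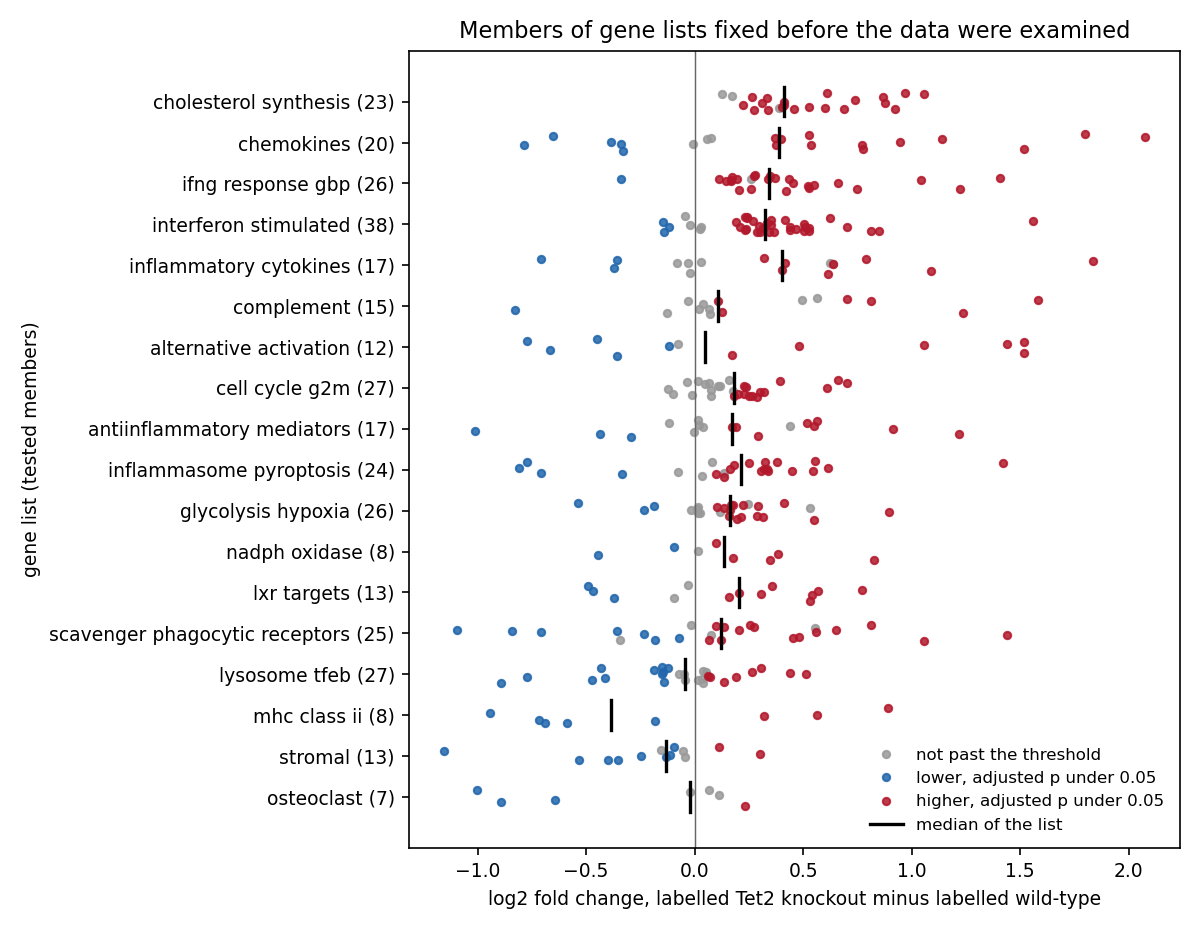
Log2 fold change (libraries labelled Tet2 knockout minus libraries labelled wild-type) of each tested member of the 15 called gene lists and of the cytokine, inflammasome and MHC class II lists; each point is a gene and each bar the median of its list. Members of the interferon and cholesterol lists lie mostly to the right of 0, with list medians of 0.32, 0.34 and 0.41, while the chemokine and alternative activation lists spread to both sides.

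Markers of connective tissue cells were called lower in the libraries labelled knockout, with 2 of 13 tested members higher and 8 lower (camera adjusted p = 0.00235; adjusted p = 0.208 with an estimated correlation). They ranged from Lum, at 1.15 ± 0.482 and 2.60 ± 0.793 CPM, to Col1a1, at 3195 ± 44.0 and 3453 ± 163 CPM in the libraries labelled knockout and wild-type, both named after their values were seen. Acta2, smooth muscle actin, fell from 645 ± 17.7 to 446 ± 11.2 CPM, Sparc from 1134 ± 41.4 to 887 ± 13 CPM and Postn by 0.40 on the log2 scale. Cxcl12 (0.30) and Col3a1 (0.11) rose, while Pdgfra (-0.04), Pdgfrb (-0.05) and Thy1 (-0.16) did not pass. General macrophage markers split, with 5 of 12 higher and 6 lower, and were not called (camera adjusted p = 0.0776; the list's median was -0.05 and its mean 0.06). Adgre1, which encodes F4/80, rose from 760 ± 15.3 to 1303 ± 13.5 CPM, Csf1r, the receptor for the growth factor that sustains macrophages, by 0.55 and Sirpa by 0.43, while C1qa fell by 0.83. The level of Col1a1 stood above those of Adgre1 and Csf1r in both groups. Bulk libraries do not show which cells a transcript came from, so the changes reported here cannot be assigned to macrophages alone. Adjusted over the list alone, the counts of both marker lists, of the osteoclast and NADPH oxidase lists and of the alternative activation list were equal. At the assumed spread of 0.1, 4 connective tissue and 6 macrophage markers passed, and Col1a1 (edgeR adjusted p = 0.609), Col3a1 (0.606) and Cxcl12 (0.0949) did not.

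Near the targeted locus 69 other genes within 10 Mb of Tet2 were tested, and 19 rose and 17 fell. At least a 2-fold change was seen in 5 of them (7.25%, against 2.43% of all tested genes). Rpl34, a ribosomal protein gene at positions 130726831 to 130730398, fell from 193 ± 2.69 to 81.6 ± 5.68 CPM (log2 change -1.24), Mcub, a subunit of the mitochondrial calcium channel, by 1.53 and the phospholipase gene Pla2g12a by 1.42. Alpk1, a kinase that senses bacterial sugars, rose from 20 ± 0.808 to 45.8 ± 2.06 CPM. Gm43351, named after its values were seen, fell by 1.36 (SE 0.40). Its level was low, 0.530 ± 0.180 CPM in the libraries labelled knockout and 1.38 ± 0.251 CPM in those labelled wild-type. The value of Rpl34 is uncertain because near-identical copies elsewhere in the genome can share its reads.

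**Figure D3:**
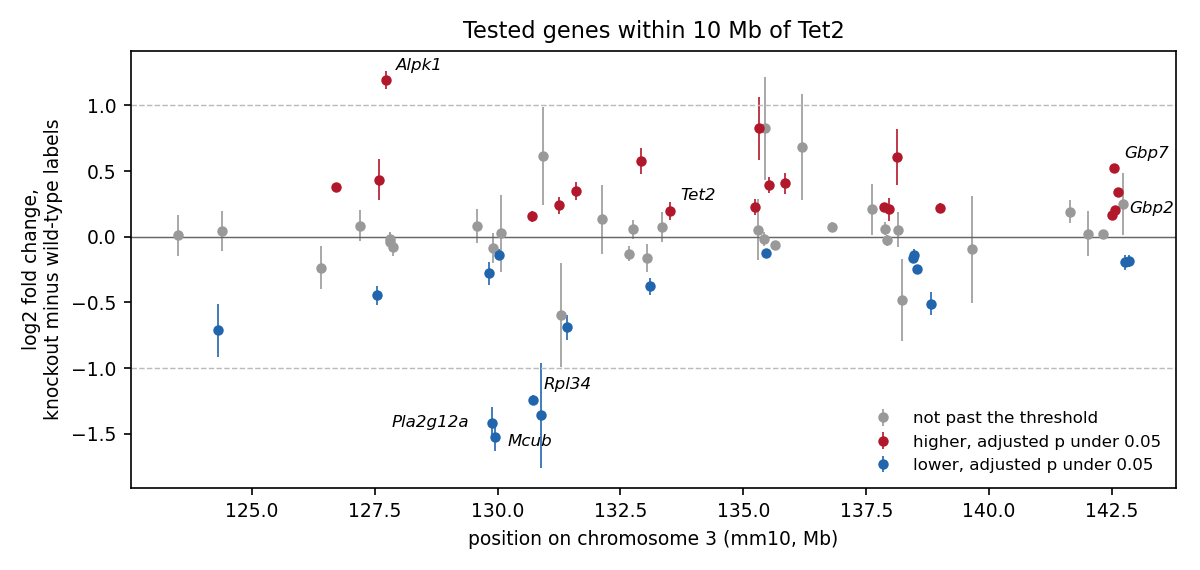
Log2 fold change (libraries labelled Tet2 knockout minus libraries labelled wild-type) of the tested genes within 10 Mb of Tet2, by position on chromosome 3 of mm10 in Mb; points are genes, bars are standard errors and dashed lines mark a log2 change of 1 in either direction. Rpl34, Mcub, Pla2g12a and Gm43351 lie below the lower dashed line and Alpk1 above the upper one.

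The 15 called lists came from 34 tested, 12 higher and 3 lower. Only the interferon, interferon-gamma response and cholesterol lists were called with an estimated correlation. Another 5 of the called lists (chemokines, complement, glycolysis and hypoxia, G2 and M phases, connective tissue) lost their call under no other alternative in which lists were tested.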

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

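The alternatives chosen only after the data had been seen were the removal of GC and length trends, the assumed spread of 0.1, and leaving out mitochondrially encoded genes or genes within 10 Mb of Tet2; the others were planned. Signs were compared only for genes called both in the main fit and in the alternative. None of these changed sign except with GC and length trends removed, where 2 did. DESeq2 kept 69.4% of the calls. It was run without the filter on low counts, on 24337 genes against 13175, and genes it gave no adjusted p counted as not called. The test and the set of genes therefore changed together. Of 167 called named genes 142 stayed past the threshold in every alternative that gave them an adjusted p, while 20 of the other 25 were lost only with the assumed spread. Some of the 142 were left out of an alternative or given no adjusted p in it. Counts of genes moved by over 1.5 times in 2 settings. DESeq2 called 1675 genes lower, with 9 lists by camera on its values, and the cause was not tested. The assumed spread gave 1885 genes, 1222 higher and 663 lower (64.8% higher against 53.0%). It is wider than the measured one and was used with edgeR's likelihood ratio test in place of the quasi-likelihood test. The cause of the larger share of higher calls was not tested. Camera with an estimated correlation called 3 lists, and fry, which asks another question, called 31. Without a filter on low counts, camera also called the lists of inflammatory cytokines (adjusted p = 0.0318), MHC class II (0.0179), immediate early genes (0.0151), macrophage markers (0.0151) and dendritic markers (0.0280). With upper-quartile scaling 47.4% of the calls were higher (2599 higher and 2883 lower), so the larger share lay on the lower side there. Leaving out 1 library gave 4725 to 5177 genes, 2580 to 2700 higher, 2138 to 2477 lower, 327 to 379 with at least a 2-fold change and 10 to 15 lists.

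Reversals among the named genes and the lists were in results that did not pass in either fit, and their cause, like that of the 2 sign changes above, was not tested. Eif2s3y was -0.00897 with upper-quartile scaling. The matrix remodelling list changed direction with DESeq2 values (camera adjusted p = 0.824), limma-voom (0.961) and GC and length trends removed (0.835), the progenitor list with DESeq2 values (0.822) and the trends removed (0.759), and the apoptosis and p53 list with the trends removed (0.835). Leaving out 1 library gave ranges of the log2 change of -0.0123 to 0.0545 for Eif2s3y, -0.154 to 0.172 for Mmp8, -0.484 to 0.00316 for Lck, -0.0161 to 0.0858 for Tnf, -0.487 to 0.0353 for Ccr2 and -0.0420 to 0.345 for Lcn2, and of the adjusted p from 0.377 to 0.992 for the matrix remodelling list.

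No pairing of libraries by replicate number was seen in the counts, though the labels do not say what the numbers mark. Deviations from the group means of libraries with the same number correlated across genes with r = 0.00365, -0.00646 and -0.0206, and other pairs with -0.0145 to 0.0216, so not every library correlated best with its own number. With the replicate block 5259 genes passed, 2789 higher and 2470 lower, 314 with at least a 2-fold change, and 15 lists were called; of the named genes Pf4 was lost (edgeR adjusted p = 0.0617). The simulated test, run at this depth, spread and number of libraries together, called 36% of 50 genes changed by a log2 of 0.25. Far fewer genes were changed there than were called in the data, so that share does not carry over to the real comparison.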

Other observations

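The tests of GC and length trends, of the stretch of 2-fold changes around Tet2, of shared reads in 2 ribosomal gene families and of exchanged labels were chosen only after the result was seen; the tests of other splits, of sex and of the share of calls near Tet2 were planned before.

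Several gene lists moved in both directions in the libraries labelled Tet2 knockout and were not called by camera. MHC class II genes fell in 5 of 8 tested members (camera adjusted p = 0.0992), with the invariant chain gene Cd74 going from 36.7 ± 4.86 to 22.2 ± 2.35 CPM (SD, n = 3 each) and H2-Aa, H2-Ab1, H2-Eb1 and Ctss also lower. The 3 that rose were H2-DMa (0.56), H2-DMb1 (0.32) and Ciita (0.89), the transactivator of the class. Toll-like receptor and NF-kappaB genes rose in 10 of 29 and fell in 7 (adjusted p = 0.386; median -0.02, mean 0.13), with Tlr1 and Tlr13 up by 1.18 and 0.45 while Tlr2 and Rela fell by 0.48 and 0.47. Immediate early genes fell in 13 of 25 and rose in 7 (adjusted p = 0.0776), among them Nr4a1 (-1.07) and Fosl2 (-0.45) against Zfp36 (0.57). Matrix remodelling genes rose in 8 of 22 and fell in 10 (camera adjusted p = 0.503, median -0.02, mean 0.04). The collagenase gene Mmp13 went from 261 ± 2.19 to 647 ± 3.21 CPM and the elastase gene Mmp12 from 1258 ± 29.9 to 828 ± 5.24 CPM. Some connective tissue markers were lower in the same libraries (Acta2 by 0.53), but Cxcl12 and Col3a1 rose and Pdgfra, Pdgfrb and Thy1 did not pass. Myeloid transcription factors split 8 and 9 of 25 (adjusted p = 0.469), Maf rising by 0.96 while Cebpa (-0.59) and Bhlhe41 (-0.63) fell. Urate and purine genes rose in 8 of 18 and fell in 3, Aprt (-0.12), Adora2b (-0.20) and Nt5e (-0.76) (adjusted p = 0.386), and the urate transporter gene Slc2a9 rose from 6.80 ± 0.864 to 10.8 ± 0.444 CPM. Called urate and purine members numbered 11, 5 with DESeq2, and 7 without knockout replicate 1 or wild-type replicate 1 or 3. Adjusted over the list alone, 4 urate and purine genes were lower, and counts of the other lists of this paragraph were equal. With an assumed spread of 0.1 in place of the measured one, 6 MHC class II, 9 Toll-like receptor and NF-kappaB, 10 immediate early, 11 matrix remodelling, 11 myeloid transcription factor and 2 urate and purine genes passed, and Ctss (edgeR adjusted p = 0.345), H2-DMb1 (0.0953), Aprt (0.596), Adora2b (0.368) and Nt5e (0.0512) did not.

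Eicosanoid genes rose in 5 of 13 and fell in 5 (adjusted p = 0.376), where Alox5ap rose by 0.81 and Pla2g7 fell by 1.42, and NRF2 and oxidative stress genes rose in 11 of 26 and fell in 8 (adjusted p = 0.598), where Hmox1 rose by 0.38 and Sqstm1 fell by 0.41. Unfolded protein and ATF4 genes rose in 14 of 24 and fell in 6 (adjusted p = 0.270), where the chaperone gene Hspa5 rose by 0.34 and Atf4 fell by 0.37. Nuclear genes of oxidative phosphorylation rose in 8 of 27 and fell in none (camera adjusted p = 0.322). With GC and length trends removed the list passed (camera adjusted p = 0.0402), in a range from 0.0402 to 0.594 over all alternatives but fry. By fry it passed as well (fry adjusted p = 0.02215). In this list 5 members passed with DESeq2 and 5 without knockout replicate 3. Mitochondrially encoded genes rose in 8 of 10, mt-Co3 fell by 0.48 and mt-Co2 did not pass. S phase genes rose in 10 of 25 and fell in 3, Rrm2 (-0.40), Slbp (-0.28) and Rfc2 (-0.19) (adjusted p = 0.322), and 8 of the 25 passed with DESeq2. Apoptosis and p53 genes rose in 5 of 22 and fell in 7 (adjusted p = 0.579; median 0.03, mean -0.00113), and DNA methylation genes rose in 8 of 21 and fell in 3, Gadd45a (-0.46), Hdac2 (-0.22) and Smug1 (-0.35) (adjusted p = 0.512), with Tet3 up by 0.26. Adjusted over the list alone the NRF2 list had 12 higher, the unfolded protein list 15 higher and 7 lower, the DNA methylation list 9 higher, and the rest of these process lists equal counts. With the assumed spread of 0.1, 5 eicosanoid, 7 NRF2, 8 unfolded protein, 0 oxidative phosphorylation, 8 mitochondrially encoded, 3 S phase, 4 apoptosis and p53 and 2 DNA methylation genes passed by edgeR, and Slbp (edgeR adjusted p = 0.141), Rfc2 (0.353), Hdac2 (0.265), Smug1 (0.0891) and Tet3 (0.141) did not. Transcription factor families named in the deposited table, 14 with at least 10 tested members and examined only after the data had been seen, gave 0 camera calls (1 at an unadjusted p under 0.05, lowest adjusted p = 0.418) and 3 calls by fry.

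Connective tissue markers aside, markers of other cell types ranged from under 1 CPM (Ccr2, at 0.622 ± 0.16 and 0.707 ± 0.302) to the abundant Fn1 (2352 ± 3.69 and 1790 ± 117). Monocyte markers rose in 2 of 6, Ms4a4c (0.72) and Fn1 (0.39), and Vcan (-0.20) fell (adjusted p = 0.369). Dendritic markers rose in 1 of 5, Xcr1 (1.06), and Itgax (-1.71) and Bst2 (-0.14) fell (adjusted p = 0.117; median 0.09, mean -0.05). Progenitor markers rose in 1 of 6, Cd93 (0.60), and Sox4 (-0.38) fell (adjusted p = 0.503; mean -0.05, with the test pointing up). Lists with fewer than 5 tested members were not tested by camera. Of these, the 3 neutrophil markers did not pass (Lcn2 stood at 5.65 ± 0.0859 and 5.02 ± 1.44 CPM), Ccr3 (1.59) rose and Gata2 (-0.76) fell among 4 of mast cells, basophils and eosinophils, Cd4 (1.75) rose among 2 of T and NK cells, the 1 B cell marker, Ebf1, did not pass and no erythroid marker was tested. Among 3 megakaryocyte markers Vwf (0.65) rose and Gp1ba fell, at 0.190 ± 0.106 and 0.796 ± 0.0615 CPM, the first a mean of under 3 counts per library, so no fold is given. The third, Pf4, at 124.5 ± 3.25 and 116.5 ± 9.01 CPM, passed narrowly (edgeR adjusted p = 0.0427) and lost its call in 11 of 18 alternatives, the replicate block given above among them. It also did not pass without knockout replicate 1 (0.212) or 3 (0.0708) or wild-type replicate 1 (0.428) or 3 (0.158), with DESeq2 factors (0.0533) or upper-quartile scaling (0.121), with the DESeq2 test (0.240), without a filter (0.0785), with GC and length trends removed (0.0526) or with the assumed spread (0.684). Only Vwf of the 3 was called with DESeq2, which gave Gp1ba no adjusted p. Gata2 did not pass with DESeq2 (adjusted p = 0.0886) or without knockout replicate 2 (edgeR adjusted p = 0.112) or wild-type replicate 3 (0.0537). Malat1 (0.36) and Kcnq1ot1 (0.68) rose and Neat1 (-0.16) and Meg3 (-0.92) fell among nuclear-retained RNAs, and 2 of 5 replication histone genes, Hist1h2bc (-0.59) and Hist1h1c (-0.36), fell. Meg3 did not pass with DESeq2 (adjusted p = 0.137) or without knockout replicate 2 (0.161) or 3 (0.0571) or wild-type replicate 1 (0.10) or 3 (0.0862), and Kcnq1ot1 did not with GC and length trends removed (0.372). Bst2 (0.483), Vcan (0.314) and Neat1 (0.441) did not pass with the assumed spread. Counts of these cell type and technical lists, and of the mitochondrially encoded genes, were equal when adjusted over the list alone.

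The first pattern is the number of called genes, 5385, against 0 as the highest of the other splits of the 6 libraries. Of 10 splits 1, the real one, reached it, and 10 splits are too few for a share under 0.05. Every other split mixes both labels on each side, so the difference between labels widens its spread. Few or no calls could come from such splits, and the 0 decides nothing. The tables argue against GC and length trends as the whole cause, since 91.7% of the calls remained with the trends removed. Sex of the cells is also argued against, because Xist had 0 counts in all 6 libraries and the largest absolute log2 difference of Uty, Kdm5d, Ddx3y and Eif2s3y was 0.165 (Uty, which passed without wild-type replicate 1, edgeR adjusted p = 0.0288), although Mid1-ps1, a Y-linked copy of an X-linked gene at 0.531 ± 0.321 and 1.36 ± 0.506 CPM, fell. Libraries drawn from a single culture per group could also give so many calls, since a difference between cultures would then be read as one of genotype, and with an assumed spread of 0.1 the number was 1885. The genotype named in the labels stays open and was not tested apart from a difference between cultures, as do variants in the segment around Tet2, which held 0.687% of the calls but has too few genes for a large share and might act on genes elsewhere.

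The second pattern is a run of 2-fold changes near Tet2 and opposite changes of ribosomal protein genes and their copies. A segment linked to the targeted locus that carries other variants stays open as an explanation of the first. Of 13014 neighbourhoods within 10 Mb of a tested gene, 1.64% had as high a share of 2-fold changes. With Rpl34 left out here, where 4 of 68 genes remain, it was 3.87%. These neighbourhoods overlap and include the stretch around Tet2 itself, and the comparison only restates the pattern. Rpl34 fell by 1.24 while its copy Rpl34-ps1 on chromosome 6 rose by 4.06, and the summed count of the family still fell by 0.518 (edgeR adjusted p = 2.0e-25). Rps3a1, on chromosome 3 but outside that stretch, fell by 0.54 while its copies Rps3a2 and Rps3a3 rose by 2.68 and 4.52, and the family sum still fell by 0.235 (edgeR adjusted p = 6.11e-13). Reads moving between near-identical copies, as a variant against the reference in the parent gene might give, may account for part of these falls; what remains in the sums (41.7% and 43.6% of the parent genes' log2 changes) stays open, since reads left out as shared were not counted here, and no variant was tested.

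The third pattern is that Tet2 was not lower in the libraries labelled knockout. Exchange of 1 library between the groups is argued against, because the lowest correlation within groups exceeded the highest between groups by 0.00768. Exchange of all labels with an allele that removes most of the transcript is argued against too, because Tet2 would then be far higher in the libraries labelled knockout, and the log2 difference was 0.198 (SE 0.07). Labels as given with an allele that removes most of the transcript are argued against as well, since Tet2 was not lower. An allele that leaves most of the transcript stays open, and under it labels as given and labels exchanged cannot be told apart. The Tet2 count only restates the pattern (0.198), and counts per exon were not analysed here. Nor does the gene count show whether the groups differ in Tet2 genotype at all.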
